A study of Mus musculus with 18 samples.

How the data were processed

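Liver DNA of BALB/c mice was profiled on 18 arrays of 2 colours, 3 for each combination of vaccination (yes or no) and day (0, 1 or 8). Per the labels' protocols, genomic DNA was sonicated, denatured and immunoprecipitated with bead-bound antibody against 5-methylcytosine. Input and IP were amplified with a whole-genome kit and labelled with Cy3 and Cy5, with no dye swap among the samples. The arrays were Agilent mouse CpG island arrays, on 9 slides of 2 arrays each, with 88737 probes besides 1036 negative and 4914 positive controls. Per the file headers, the authors extracted each spot's intensity with Feature Extraction 12.0.3.1 and its ChIP protocol, which subtracts a spatially detrended background and applies a linear dye normalization, with probe coordinates on mm9. The deposited log10 values of the series table equalled the log ratio of the same array's scanner output within 1e-06 for all 88737 probes on every array, so their scale and direction (IP over input) are settled, and they were not centred further: their medians lay at or near 0. Where both channels are at the software's floor, these deposited log10 ratios are 0, at 5.34 to 37.4% of the probes on the arrays in place and 62.4 to 72.9% on the displaced ones, while the processed intensities of the same spots keep a ratio.

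The log2 ratio of processed red over green intensity was centred on each array's median, with no loess or quantile step, since on such arrays many probes carry signal. Control spots and probes marked as non-uniform in either channel on any array were left out, which removed 12396 probes and left 76015. Of all probes, 88411 had coordinates and 326 had none. Neighbouring probes up to 1000 bp apart, the upper fragment size of the protocol, were joined into regions, and a region's value was the mean over at least 2 probes, which left 13910 regions. The design fixed before the data were examined took gene promoters as the unit. As the files name no gene and no promoter and the gene table supplied is on another build, regions took their place, and the gene lists fixed for the same purpose, with their set tests, were not run. That design also asked for input well above background on all 18 arrays, which no probe met (0 left), so the fit without this filter, one of the alternatives fixed at that time, is the one reported. Alternatives that use mean spot signals used median signals.

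Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on 6 group means, 12 residual degrees of freedom, two-sided). Calls were made at an adjusted p under 0.05 by Benjamini and Hochberg's method within each of 11 contrasts: vaccinated minus non-vaccinated at each day and averaged, each later day minus day 0 in each arm, day 8 minus day 0 averaged over the arms, and the differences of these changes between arms. The contrasts, the tests, the groups of arrays and the alternatives were fixed before the data were examined, except those named as chosen after seeing the data. The rule for naming regions was also fixed then. It took up to 12 regions each way with the largest difference among those called, and where fewer than 6 were called, all of these plus the 5 highest and 5 lowest by moderated statistic among regions whose groups do not overlap. As the files pair no region with a gene, at most the first 2 each way are printed. A region is said to have no fold where a channel was not well above background on any array of a group. Background was read at the listed positions, so on displaced arrays it came in large part from other spots where the matching described below holds.

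Positions were checked by the Spearman correlation of red median signals between arrays. The 10 arrays linked by a rho over 0.25 were taken as having their grid in place. For the others, windows of 33 spot lines by 41 steps of the staggered columns were set against the mean brightness of those 10 at shifts of up to 7 lines and 5 steps. A shift was accepted at a local correlation of at least 0.3 that led the next shift by 0.1. This placed 65.7 to 100% of the spots of the 8 displaced arrays, and 4022 regions had at least 2 probes on all 18 arrays. On an array in place that was moved on purpose as a whole by each of 3 known shifts, the procedure placed 100% of the spots, all at the true shift. The displaced arrays had 1 to 7 shifts that each held over 1% of the matched spots. Placement in patches was therefore not covered by that test. The match used brightness only, so the correlation of log ratios between neighbouring probes, 50 to 400 bp apart, was a separate check.

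The fit was tested on simulated data with 200 of 13910 regions changed. For vaccinated minus non-vaccinated at day 0, with equal spread on all arrays, it recovered 8.96% of differences of 1, 71.6% of 2 and 92.4% of 3 on the log2 scale, with 5 false calls among 120, and with each array's own spread 5.97, 62.7 and 87.9%, with 2 false calls among 106. Each array's own spread was its residual SD around the group means, not the SD of its log ratios. For day 8 minus day 0 in vaccinated mice, data with no change but each array's own spread gave 3 calls and 1720 regions with an unadjusted p under 0.05. With 200 regions changed and each array's own spread, 62 of 180 calls were false in that comparison and 85 of 199 for vaccinated minus non-vaccinated at day 8. Single values were compared with exact permutation tests, enumerated in Python 3.11.15 with numpy 2.4.6, and scipy 1.17.1 adjusted their p-values. Comparisons of 3 arrays with 3 cannot give an exact p under 0.1.

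The alternatives fixed beforehand were normexp background correction (offset 50), loess within arrays, scale and quantile normalization between arrays, a trended robust variance, the median over probes, at least 4 probes per region, single probes, the deposited log ratios, slide or scan day as a block, the replicate number as a block, array weights, only the groups of a contrast, another threshold and each array left out in turn. Scale normalization gave all arrays the same median absolute log ratio of probes, which need not make their SDs equal. Realigned spots, the 10 arrays in place and single scan days were added after seeing the data. Corrections for probe composition and the choice of promoter against other probes were not run, as sequences and gene assignments were not used here.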

Results

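DNA methylation in liver was compared between BALB/c mice, an inbred laboratory strain, that had or had not been vaccinated against blood-stage malaria caused by Plasmodium chabaudi, a parasite of rodents. Livers were sampled on days 0, 1 and 8, and the labels do not say from which event the days count. Each of the 6 combinations of vaccination and day had 3 arrays, 18 in all. Methylated fragments were pulled down with an antibody against 5-methylcytosine (the IP, red dye) and hybridised together with untreated input DNA (green dye) to an array of mouse CpG islands, the CG-rich stretches that overlap many promoters. The measure was the log2 ratio of IP over input. A higher value stands for more methylated DNA relative to the other islands on the same array only where the input does not account for it. Probes were joined into 14230 regions of at least 2 probes on genome build mm9, with a median of 5 probes and 663.5 bp. Of these regions, 391 lay on the X chromosome. The files do not pair probes with genes, so regions are named by position. The labels do not state that the 3 arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

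On 8 of the 18 arrays few probes had signal above background, and these 8 carried their spots in other positions than the other 10. On the 10 arrays whose spot grid lay in place, IP signals of any pair of arrays correlated across probes with Spearman's rho between 0.298 and 0.888. On the other 8, the correlation with those 10 arrays was between -0.0519 and 0.16. These 8 displaced arrays were non-vaccinated day 1 replicates 1 and 3, all 3 vaccinated day 1 arrays, non-vaccinated day 8 replicates 1 and 2, and vaccinated day 8 replicate 2. The grid lay in place on all 6 day 0 arrays, on 1 non-vaccinated day 1 array, on 1 non-vaccinated day 8 array and on 2 vaccinated day 8 arrays. On the displaced arrays, 0 to 26.1% of the spots were matched at their listed position, so the log ratio listed for a region came in large part from other spots where this matching holds. Moving each patch of spots to the position where its brightness matched the other arrays brought the correlation of neighbouring probes from at most 0.00891 to between 0.116 and 0.416. The values given here are those listed in the files. Realigned values and those of the 10 arrays in place are given beside them for part of the regions. Input was well above background at 5.05 to 62.5% of the probes on the 10 arrays in place and at 4.6 to 9.15% on the displaced ones.

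**Figure D1:**
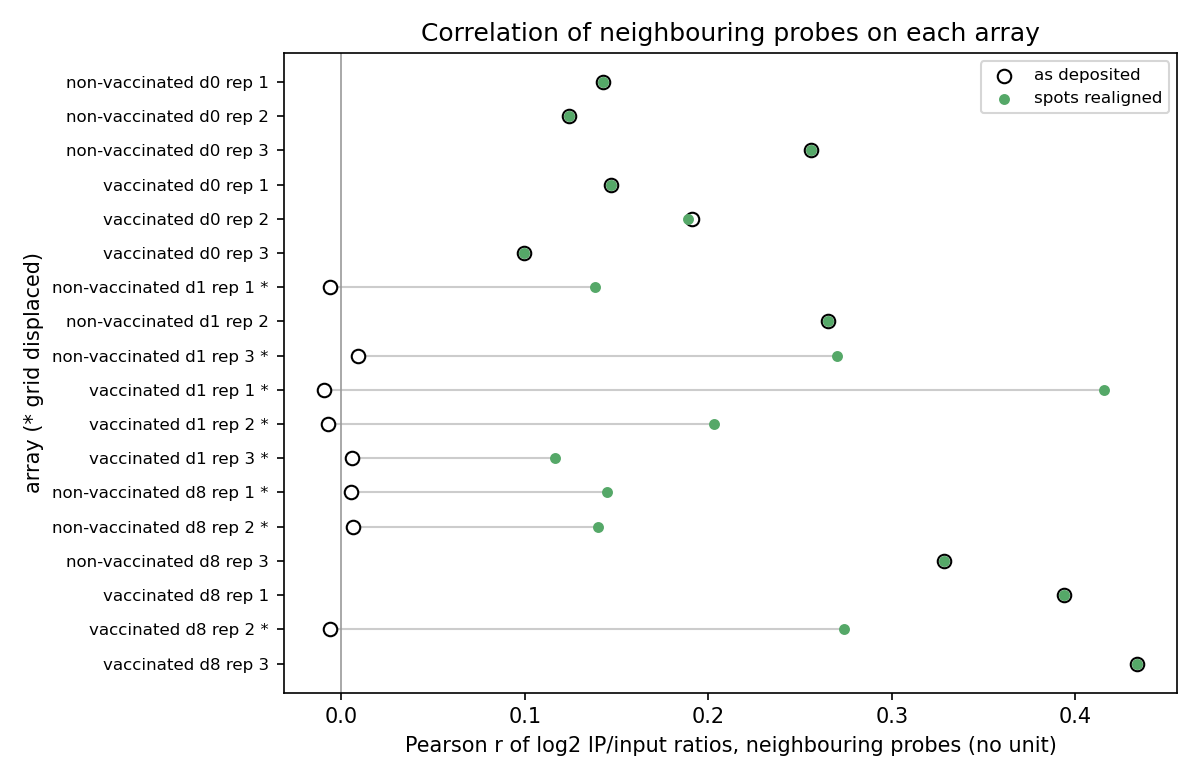
Pearson correlation (x axis, no unit) of the log2 IP over input ratios of probes 50 to 400 bp apart on each of the 18 arrays (y axis), as deposited (open circles) and after spots were realigned (filled circles). The 8 displaced arrays, marked with an asterisk, lie at or below 0.00891 as deposited and between 0.116 and 0.416 after realignment.

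At day 0, the clearest difference between vaccinated and non-vaccinated mice lay in a region of chromosome 8, from 113521522 to 113521836. Its log2 ratio was -2.92 ± 0.70 (SD, n = 3) in vaccinated and 0.20 ± 0.31 (SD, n = 3) in non-vaccinated mice, a difference of -3.12 ± 0.40 (SE; limma adjusted p = 0.00686), with every vaccinated array below every non-vaccinated one. The difference came from a brighter input: the input of its 4 probes was 2.71 ± 0.48 (SD, n = 3) above the array median on the log2 scale in vaccinated and -0.05 ± 0.58 (SD, n = 3) in non-vaccinated mice, while the IP was -0.57 ± 0.92 and 0.10 ± 0.38 (SD, n = 3). A difference carried by the input is not read here as one of methylation. On the 1 slide that held an array of each group, the values were -3.15 for vaccinated replicate 1 and 0.54 for non-vaccinated replicate 3. The other region that was lower in vaccinated mice, on chromosome 8 from 86716472 to 86716845 (limma adjusted p = 0.0342), had an input not well above background on any of the 3 non-vaccinated arrays, so no fold is given.

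These 2 regions were all that passed among 13910 tested with limma, and 1363 had an unadjusted p under 0.05, where 695.5 are expected by chance. With slide as a fixed block 2 regions passed and with scan day as a fixed block 3, and in both fits 0 of them were among these 2. Neither passed when normexp background correction replaced the processed signals, or with scale normalization between arrays. Neither passed when only the 10 arrays in place were fitted, where the first region had a difference of -3.12 (limma adjusted p = 0.54). With normexp its difference was -1.54 (limma adjusted p = 1), and with normexp after realignment -0.90 (limma adjusted p = 0.945). With the deposited log ratios in place of the processed signals 1 region passed, the first one, at a difference of -3.26 (limma adjusted p = 0.00203), and over 8 alternatives for this region the adjusted p ran from 0.000495 to 1. Its input was well above background on all 6 arrays and its IP on 2 vaccinated and 3 non-vaccinated arrays.

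**Figure D2:**
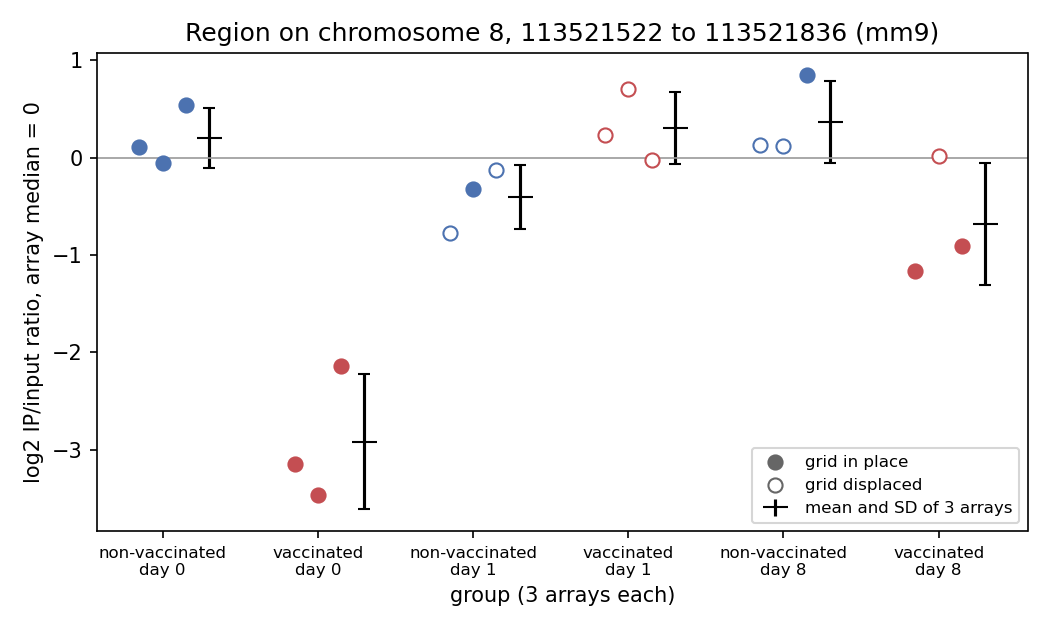
Log2 IP over input ratio (y axis, array median at 0) of the region on chromosome 8 from 113521522 to 113521836 on each of the 18 arrays, by group (x axis), with the mean and SD of the 3 arrays of a group in black. The 3 vaccinated day 0 arrays lie between -3.47 and -2.14, below the other 15, and open circles mark the displaced arrays.

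At day 1, no region differed between vaccinated and non-vaccinated mice (0 of 13910 with limma, 117 with an unadjusted p under 0.05, 0 after realignment). Among regions whose groups did not overlap, which chance gives at 10% of regions, the highest moderated statistic was on chromosome 10 from 85391079 to 85391658, with a difference of 1.14 ± 0.29 (SE; limma adjusted p = 1). The lowest was on chromosome 19 from 28085810 to 28086563 (limma adjusted p = 1), where the IP was not well above background on any vaccinated array, so no fold is given. Realigned, the first had a difference of 0.09 (limma adjusted p = 0.999). At its listed spots, both channels were well above background on 1 vaccinated and 2 non-vaccinated arrays. On vaccinated replicates 1 to 3, the matching found 0, 1 and 0 of its 4 probes at their listed position. For the region on chromosome 19 it found 0 of 6 on each of them. Since all 3 vaccinated day 1 arrays were displaced, the arms could not be compared at this day on arrays in place.

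At day 8, no region differed between the arms either (0 of 13910 with limma), although 1743 had an unadjusted p under 0.05. The region on chromosome 19 from 5731362 to 5731828 was at 1.93 ± 0.58 (SD, n = 3) in vaccinated and -0.44 ± 0.11 (SD, n = 3) in non-vaccinated mice, and that on chromosome 2 from 29948893 to 29949559 at -2.32 ± 1.39 and 0.76 ± 0.58 (SD, n = 3), both with a limma adjusted p of 0.137. Input was well above background on 1 array of each arm for the first and on 3 vaccinated and 1 non-vaccinated array for the second. On the 10 arrays in place, these differences were 2.68 (limma adjusted p = 0.235) and -4.38 (limma adjusted p = 0.0704), with 1 non-vaccinated and 2 vaccinated arrays. On chromosome 2 the difference lay mostly in the input, at 2.28 ± 1.00 in vaccinated and 0.03 ± 0.45 in non-vaccinated mice, with the IP at -0.13 ± 0.87 and 0.74 ± 0.10 (SD, n = 3). On chromosome 19 it lay in the IP, at 1.93 ± 0.59 and -0.19 ± 0.28, with the input at 0.08 ± 0.29 and 0.29 ± 0.24 (SD, n = 3). Without vaccinated day 8 replicate 2, a displaced array, 870 regions passed. With slide as a block 316 passed, a fit that rests on the 1 day 8 slide with an array of each arm, and 1 passed after realignment with normexp.

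Averaged over the 3 days, no region differed between vaccinated and non-vaccinated mice (0 of 13910 with limma; 987 with an unadjusted p under 0.05; smallest adjusted p 0.403). No region had all 9 vaccinated arrays on 1 side of all 9 non-vaccinated ones. On simulated data of 13910 regions, this comparison recovered 49.3% of differences of 1 and 97% of differences of 2 on the log2 scale with equal spread on all arrays, and 58.2 and 95.5% with each array's own spread. Leaving out vaccinated day 8 replicate 2 gave 42 regions.

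In non-vaccinated mice, no region changed from day 0 to day 1 or from day 0 to day 8 (0 of 13910 with limma in both, with 313 and 690 at an unadjusted p under 0.05). On chromosome 4 from 148960239 to 148961751, the log2 ratio was -2.25 ± 1.33 at day 0 and 0.59 ± 0.86 at day 1 (SD, n = 3; limma adjusted p = 1). On chromosome 15 from 79659103 to 79659554, it was 0.89 ± 0.63 at day 0 and -1.24 ± 1.20 at day 1 (SD, n = 3; limma adjusted p = 1). From day 0 to day 8, the region on chromosome 7 from 52743944 to 52744250 differed by 2.07 ± 0.45 (SE; limma adjusted p = 0.993) and that on chromosome 17 from 24786775 to 24787046 by -1.15 ± 0.30 (SE; limma adjusted p = 0.993). At each of these 4 regions, at least 1 channel was well above background on only 1 array of the later day. As listed, the 2 differences for day 1 were 2.84 and -2.14. On the arrays in place, with 1 array of the later day, the 4 differences were 3.46, -3.45, 2.34 and -1.11 in this order. After realignment with normexp, those on chromosomes 15 and 7 were -1.19 and 1.07, and those on chromosomes 4 and 17 could not be tested. Without non-vaccinated day 0 replicate 2, 1 region passed at day 1 and 2 at day 8.

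In vaccinated mice, 9 regions were higher at day 1 than at day 0 and none was lower (limma, 13910 regions, 1613 with an unadjusted p under 0.05). Among them was the region on chromosome 8 from 113521522 to 113521836, at 0.30 ± 0.37 on day 1 and -2.92 ± 0.70 on day 0 (SD, n = 3; limma adjusted p = 0.00438). At day 1 its IP was well above background on 2 arrays and its input on 1. The next by size, on chromosome 10 from 44249436 to 44249660 (limma adjusted p = 0.042), had no array of either day with an IP well above background, so no fold is given. All 3 day 1 arrays were displaced, and on replicates 1 to 3 the matching found 0, 1 and 0 of the 4 probes of the first region at their listed position. Of the 9, 2 passed with slide as a random block, 0 with scan day as a fixed block and 0 with normexp. Leaving out vaccinated day 0 replicate 1 or day 1 replicate 2 gave 0 regions, and leaving out vaccinated day 0 replicate 3 or day 1 replicate 1 or 3 gave 1. The first region had a difference of 3.37 with the deposited log ratios (limma adjusted p = 0.00129), the only call made with them, 1.84 with normexp and spots left as listed (limma adjusted p = 1) and 0.70 with normexp after realignment (limma adjusted p = 0.999). With processed signals, the median ratio of spots at the software's floor was -1.25 to -1.02 on the day 0 arrays and 0.00 to 0.03 on the day 1 arrays. After realignment with processed signals 27 of 4022 regions passed.

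From day 0 to day 8, vaccinated mice had 592 regions with higher and 185 with lower log ratios, 777 in all and 3437 at an unadjusted p under 0.05 (limma, 13910 regions). At day 0, 40.8% of the probes in these regions were at the software's floor, against 28.6% in all tested. The median ratio of spots at the floor was -1.25 to -1.02 on the day 0 arrays and -0.02 to 1.08 on the day 8 arrays. The largest increase was on chromosome 12 from 81269443 to 81269617, from -1.36 ± 2.32 to 3.42 ± 3.45 (SD, n = 3), a difference of 4.78 ± 1.27 (SE; limma adjusted p = 0.038), with input well above background on 1 array of each day. The next, on chromosome 11 from 75813354 to 75813504 (limma adjusted p = 0.00983), had no day 8 array with an input well above background. The largest decreases, on chromosome 9 from 22063984 to 22064339 (limma adjusted p = 0.0226) and on chromosome 13 from 55201194 to 55201346 (limma adjusted p = 0.0107), had no day 0 array with an input well above background, so no fold is given for these 3. Both decreases lay largely in the input, at 2.50 ± 2.78 and 3.05 ± 1.87 at day 8 and 0.27 ± 0.27 and -0.32 ± 0.25 at day 0 (SD, n = 3). The increase on chromosome 12 lay mostly in the IP, at -0.65 ± 0.93 at day 0 and 3.16 ± 0.85 at day 8 (SD, n = 3). On the 10 arrays in place, 631 regions passed, 342 of them also among the 777, and the difference on chromosome 12 was 6.63.

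The 777 depended on how the ratios were formed. With the deposited log ratios no region passed, the median size of the 777 differences going from 1.82 to 1.32 on the log2 scale with a median SE of 0.427 and 0.422, and 2448 regions had an unadjusted p under 0.05. No region passed with normexp, with scale or quantile normalisation or with scan day as a block, and 1 passed with loess or with array weights. The losses differed. With quantile normalisation 94.9% of the 777 still had an unadjusted limma p under 0.05 (median size 1.17, SE 0.383). This was 59.5% with normexp (0.78, SE 0.321) and 41.6% with scale normalisation (0.84, SE 0.454). With spots realigned, no region passed with normexp and 398 with processed signals. No scan day held arrays of both day 0 and day 8, so the fit with scan day as a block compared these days only through the day 1 arrays, and no comparison within a scan day could be made. Without vaccinated day 8 replicate 2, 2259 regions passed, and without vaccinated day 0 replicate 3, 48 passed.

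Averaged over both arms, 110 regions differed between day 8 and day 0, all but 5 of them higher at day 8 (limma, 13910 regions, 2647 with an unadjusted p under 0.05). Among the higher ones were the regions on chromosome 11 from 75813354 to 75813504 (limma adjusted p = 0.0347) and on chromosome 14 from 118933111 to 118933446 (limma adjusted p = 0.0495). Among the lower ones were the regions on chromosome 13 from 55201194 to 55201346 and on chromosome 15 from 75751654 to 75751991 (limma adjusted p = 0.0471 for both). At each of these 4 regions, input was not well above background on any array of at least 1 of the 4 groups, so no fold is given. The count was 17 with slide as a random block, 0 without non-vaccinated day 0 replicate 3 and 1247 without vaccinated day 8 replicate 2. With the deposited log ratios no region passed, and after realignment 4 passed with normexp, 0 of them among the 110. The 10 arrays in place hold 1 non-vaccinated day 8 array, so their count with processed signals and no input filter is not given. Their counts under other processing, given further below, rest on that same array for non-vaccinated day 8. With processed signals after realignment 89 of 4022 regions passed, 7 of them among the 110, of which 25 could be tested there.

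The change from day 0 to day 1 differed between vaccinated and non-vaccinated mice at 1 region, again that on chromosome 8 from 113521522 to 113521836, by 3.83 ± 0.56 (SE; limma adjusted p = 0.0435; 704 of 13910 regions at an unadjusted p under 0.05). Of the day 1 arrays, only non-vaccinated replicate 2 had its grid in place. On each of the others the matching found 0 or 1 of the 4 probes at their listed position. Where it holds, the day 1 values thus came mostly from other spots. With slide as a random block no region passed (smallest limma adjusted p 0.0628; 602 regions at an unadjusted p under 0.05), nor with slide, scan day or replicate number as a fixed block. The call was kept with loess, quantile normalisation, the median over probes, at least 4 probes, array weights and the deposited log ratios, where the difference was 3.72 (limma adjusted p = 0.0349). Most of this difference was the one of -3.12 at day 0, which came from a brighter input and is not read as one of methylation. With normexp the interaction difference was 1.77 (limma adjusted p = 1) with spots left as listed and 0.92 (limma adjusted p = 0.999) after realignment. The realigned fit used fewer probes of this region, those placed on all 18 arrays, and moved none of its day 0 spots. Its smaller difference is thus not one of positions alone. The change from day 0 to day 8 differed between the arms at no region (0 of 13910 with limma, 1564 at an unadjusted p under 0.05). The lowest moderated statistic there was on chromosome 18 from 36894543 to 36895023 (limma adjusted p = 0.0714), where input was not well above background on any vaccinated day 0 array. The highest was on chromosome 19 from 5272914 to 5273513 (limma adjusted p = 0.0714), where input was not well above background on any vaccinated day 8 or day 0 array, so no fold is given for both. Without vaccinated day 8 replicate 2, 335 regions passed in this comparison.

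Regions on the X chromosome stood higher against autosomal regions at day 8 than at day 0, a comparison chosen after the values had been seen. After realignment, the median log2 ratio of X regions minus that of autosomal regions was 0.12 ± 0.07 (SD, n = 6) at day 8 and 0.00 ± 0.03 (SD, n = 6) at day 0, with all 6 day 8 arrays above all 6 day 0 arrays. With spots left as listed the difference was 0.07 (two-sided exact permutation p = 0.0411), with 2 day 8 arrays below the highest day 0 array. After realignment the difference was 0.11 (two-sided exact permutation p = 0.00216 over 924 splits of single arrays, the smallest they can give; adjusted p = 0.0433 over 20 chromosomes tested in the same way). As every slide held arrays of 1 day only and arrays of a slide are alike, whole slides were also split, 3 against 3, with a two-sided exact permutation p of 0.1 over 20 splits, the smallest they can give. None of the 19 autosomes separated the days without overlap, and their differences lay between -0.03 and 0.03. Some autosomes shifted too, though less than X. Chromosomes 5, 9, 11 and 19 were lower and 6 and 13 higher at day 8 (two-sided exact permutation p from 0.0216 to 0.0498 unadjusted, 0.142 adjusted). Probe composition, which was not corrected for, was not set apart from these shifts or from that of X. Both arms were alike at day 8, at 0.12 ± 0.06 in non-vaccinated and 0.12 ± 0.09 in vaccinated mice (SD, n = 3). On the arrays in place, 3 of day 8 and 6 of day 0, the difference was 0.14 (two-sided exact permutation p = 0.0119). No scan day held both days. Within the scan day of the day 8 arrays, the 6 day 8 arrays were at 0.12 ± 0.07 and 2 day 1 arrays at 0.05 ± 0.01 (SD; two-sided exact permutation p = 0.179). Over all days, the 9 vaccinated and 9 non-vaccinated arrays differed by 0.01 (two-sided exact permutation p = 0.666).

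**Figure D3:**
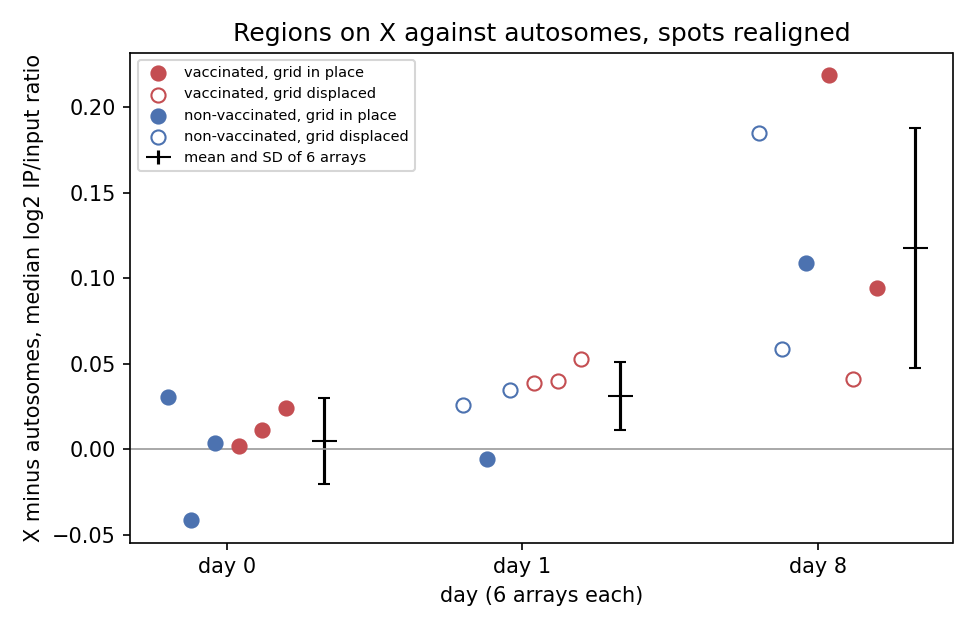
Median log2 IP over input ratio of X regions minus that of autosomal regions (y axis) on each of the 18 arrays after realignment, by day (x axis), with the mean and SD of the 6 arrays of a day in black. The 6 day 8 arrays lie between 0.04 and 0.22 and the 6 day 0 arrays between -0.04 and 0.03.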

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

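The interaction test was planned, while the tests of explanations and the counts of splits in this part were chosen after the results were seen, and the bounds and the deciding value of the tests of a wider spread were revised after their outcome was known. The change from day 0 to day 1 differed between vaccinated and non-vaccinated mice by 3.83 on the log2 scale at the region on chromosome 8 from 113521522 to 113521836, which is listed here because the difference itself passed the limma test. Of 100 splits of the same 12 arrays, the real one called 1 region and the highest of the others 0, which repeats that single call and leaves chance open. With slide as a random block the call was lost (limma adjusted p = 0.0628), and with the deposited log ratios it was kept (3.72, limma adjusted p = 0.0349). Most of it was the difference of -3.12 between the arms at day 0, which came from a brighter input and is not read as one of methylation. With normexp the interaction difference was 1.77 (limma adjusted p = 1) with spots left as listed and 0.92 (limma adjusted p = 0.999) after realignment. The call was lost without any one of 11 of the 12 arrays, all but vaccinated day 0 replicate 3. On every day 1 array except non-vaccinated replicate 2, the matching found 0 or 1 of the region's 4 probes at their listed position. Where it holds, the listed day 1 values came mostly from other spots.

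For the 8 arrays that did not share spot positions with the other 10, the lowest of their correlations between neighbouring probes after realignment was 0.116. This argues against signals unrelated to the probes. A hybridisation without specific signal stays open, since a likeness of neighbouring probes through their composition was not set apart. A spot grid laid off the printed spots is the likely source, since the median of these correlations was 0.174, near the 0.224 of the 10 arrays in place. No biological explanation was tested, as the design gives none.

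Most calls fell between day 0 and day 8 in vaccinated mice, 777 regions, and in 10 splits of the 6 arrays the highest of the others was 4, too few splits for a share under 0.05. A wider spread of log ratios on the day 8 arrays stays open. With scale normalization, 536 regions had an unadjusted p under 0.05 against 695.5 by chance. That step equalised the median absolute log ratio, which on displaced arrays may rest largely on spots at the floor. It does not show the outcome at equal SDs. Simulated data with no change and each array's residual SD gave 3 calls and 1720 regions at an unadjusted p under 0.05, against 777 and 3437 observed. On vaccinated day 8 replicates 1 to 3 these residual SDs were 0.849, 0.659 and 0.889, while the SDs of the log ratios were 1.17, 0.41 and 1.25. The simulation therefore cannot decide this. With scale normalization the median size of the 777 differences went from 1.82 (SE 0.427) to 0.84 (SE 0.454), although a true change would widen the spread too. Only the day 8 arrays in place were wide, with SDs of 1.17 and 1.25 on vaccinated replicates 1 and 3 and 0.86 on non-vaccinated replicate 3. The displaced day 8 arrays, at 0.36 to 0.47, were narrower than every day 0 array (0.54 to 0.76). Spots at the software floor stay open, as the deposited log ratios, 0 at such spots, left a median size of 1.32 (SE 0.422) and no call, the size having shrunk at a like SE. With processed signals the median of such spots was -1.25, -1.15 and -1.02 on the vaccinated day 0 arrays. It was -0.02, 0.00 and 1.08 on the vaccinated day 8 arrays, which by itself gives higher values at day 8. At vaccinated day 0 they made up 40.8% of the probes in the 777 regions and 28.6% in all tested, at day 8 34.6 and 32.8%. The counts, 0 with those ratios, 1 with loess and 2259 without vaccinated day 8 replicate 2, were looked at first and set aside for the sizes, and a change of methylation by day 8 cannot be told apart from the scan day, since 0 scan days held arrays of both days.

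For the higher X values at day 8, single arrays argue against a wider spread of the day 8 arrays as the whole cause. Whole slides, 3 against 3, cannot decide this. After division by each array's SD, day 8 stood above day 0 without overlap (two-sided exact permutation p = 0.00216 over single arrays), also on the arrays in place alone, 3 of day 8 and 6 of day 0 (two-sided exact permutation p = 0.0119), and the 3 displaced day 8 arrays, whose values rest on realignment and whose spread was no wider than that of the widest day 0 array, were at 0.09 ± 0.08 (SD, n = 3) against 0.00 ± 0.03 (SD, n = 6). The scan day stays open: day 1 arrays scanned with the day 8 arrays were at 0.05 ± 0.01 (SD, n = 2) and the others at 0.02 ± 0.02 (SD, n = 4; two-sided exact permutation p = 0.2). A change of X methylation by day 8 stays open as well, with a two-sided exact permutation p of 0.179 against the 2 day 1 arrays of the same scan day. The 3 slides of each day limit the pattern itself, with a p of 0.1 where slides are kept whole (two-sided exact permutation). After division by the SD this p was 0.1 too, the smallest that whole slides can give. It was the deciding value for the spread until that was changed, with both values seen, to the p over single arrays.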

How the results depend on the processing

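Realigned spots, the 10 arrays in place and single scan days were chosen after the data were seen, the other alternatives before. In this part, counts are regions called with limma. No cause of a moved count was tested, except where fewer regions or arrays were fitted.

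Of the 11 comparisons, vaccinated against non-vaccinated mice at day 1 kept its count of 0 in 22 of 23 alternatives besides leaving out arrays, the averaged comparison of the arms in 20 of 22, non-vaccinated mice from day 0 to day 1 in 24 of 26 and from day 0 to day 8 in 22 of 25. None of the 22 alternatives left the count for day 1 in vaccinated mice within 1.5 times of its 9.

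For vaccinated against non-vaccinated mice at day 0 (2 as reported), the count was 0 with normexp, scale normalization, a trended robust variance or only the groups of the contrast. It was 1 with loess, quantile normalization, at least 4 probes, the deposited log ratios, slide as a random block or single probes, 50 with the median over probes and 39 with array weights. Realigned, it was 0 with normexp alone or with loess, slide, scale or weights, and 6 with processed signals. It was 0 on the 10 arrays in place, whether processed, with normexp, with loess or with input well above background (102 regions), and 0 within 1 scan day.

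For vaccinated mice from day 0 to day 1 (9 as reported), the count was 0 with normexp, scale normalization or scan day as a block. It was 1 with loess, quantile normalization, the trended robust variance, the deposited log ratios or single probes, 2 with slide as a random block, 5 with at least 4 probes and 5 with the replicate number as a block. It rose to 36 with only the groups of the contrast, 164 with the median and 521 with array weights. Realigned, it was 27 with processed signals and 0 with each of the 5 normexp fits, and 0 within 1 scan day.

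For vaccinated mice from day 0 to day 8 (777 as reported), the count was 0 with normexp, scale or quantile normalization, the deposited log ratios, scan day as a block or only the groups of the contrast. It was 1 with loess, 1 with array weights, 486 with at least 4 probes, 1415 with the median and 4373 with single probes. Realigned, it was 398 with processed signals, 27 with normexp and loess and 0 with the other 4 normexp fits. On the arrays in place it was 181 with normexp, 64 with loess and 0 with input well above background (102 regions). With slide as a random block 542 passed, all among the 777, and with the replicate block 599, 582 of them among the 777.

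Averaged over the arms, day 8 against day 0 (110 as reported) gave 0 with normexp, loess, scale or quantile normalization, the deposited log ratios, scan day as a block or only the groups of the contrast, 30 with at least 4 probes, 17 with slide as a random block, 23 with the replicate block, 7 with array weights and 7 with single probes. Realigned, it was 89 with processed signals and 4 with normexp, and normexp gave 4 with slide, 14 with loess, 1 with scale and 0 with weights. The arrays in place gave 25 with normexp, 254 with loess and 0 with input well above background (102 regions).

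For the day 1 interaction (1 as reported), the count was 0 with normexp, scale normalization, the trended robust variance, slide as a random or fixed block, scan day as a block, the replicate block, single probes, all 6 realigned fits and 1 scan day, and the call was kept with loess, quantile normalization, the median, at least 4 probes, array weights and the deposited log ratios. For the day 8 interaction (0 as reported), it was 26 with slide and 2 with scan day as a fixed block, 2 realigned with processed signals and 1 with normexp and weights.

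Vaccinated against non-vaccinated mice at day 8 (0 as reported) gave 316 with slide as a fixed block. Realigned, it gave 1 with normexp, 1 with slide, 9 with loess, 2 with weights and 3 with processed signals. The averaged comparison gave 1 with slide as a fixed block. Non-vaccinated mice gave 2 from day 0 to day 1 with quantile normalization and, from day 0 to day 8, 4 realigned with normexp and weights. For day 8 in these comparisons, counts on the arrays in place are not given, as 1 non-vaccinated array is left. With slide as a fixed block, comparisons of days could not be fitted, as no slide held arrays of 2 days.

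At an unadjusted p under 0.01 and 1.5-fold, the counts for vaccinated against non-vaccinated mice were 382 at day 0, 9 at day 1, 510 at day 8 and 186 averaged. They were 41 and 124 for days 1 and 8 in non-vaccinated mice, 528 and 1506 in vaccinated mice, 1045 averaged over the arms, and 135 and 425 for the interactions.

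Leaving out each array in turn gave, for vaccinated against non-vaccinated mice, 0 to 6 at day 0, 0 to 0 at day 1, 0 to 870 at day 8 and 0 to 42 averaged. Non-vaccinated mice gave 0 to 1 for day 1 and 0 to 2 for day 8, vaccinated mice 0 to 9 and 48 to 2259, the average over the arms 0 to 1247, and the interactions 0 to 1 and 0 to 335. Without vaccinated day 8 replicate 2, the counts were 870 at day 8, 42 averaged over days, 2259 in vaccinated mice, 1247 averaged over the arms and 335 for the day 8 interaction. Without vaccinated day 8 replicate 3, they were 1 at day 8 and 316 in vaccinated mice.

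For vaccinated against non-vaccinated mice at day 0, the count was 0 without non-vaccinated day 0 replicate 1 or vaccinated day 0 replicate 1, 6 without vaccinated day 0 replicate 2 and 1 without vaccinated day 0 replicate 3. Day 8 against day 0 in vaccinated mice gave 179, 444 and 48 without vaccinated day 0 replicates 1, 2 and 3. Day 1 against day 0 in vaccinated mice gave 0 without vaccinated day 0 replicate 1 or day 1 replicate 2, and 1 without vaccinated day 0 replicate 3 or day 1 replicates 1 or 3. The average over the arms gave 72 and 0 without non-vaccinated day 0 replicates 1 and 3, 21 and 8 without vaccinated day 0 replicates 1 and 3, and 9, 25 and 12 without non-vaccinated day 8 replicates 1, 2 and 3. Without non-vaccinated day 0 replicate 2, non-vaccinated mice gave 1 for day 1 and 2 for day 8, and the day 8 interaction 1.

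Among 184 values of named regions under alternatives chosen beforehand, 106 kept their side of the threshold and direction, 76 lost the call, 1 gained it and 1 reversed. Most of the 106 belong to regions not called as reported, which stayed uncalled. Only called regions can lose a call, and among their values the call was lost more often than kept. Under normexp the region on chromosome 10 from 44249436 to 44249660, higher at day 1 than at day 0 in vaccinated mice, stood at -0.14, and its IP was not well above background on any of these arrays. Under quantile normalization the region on chromosome 4 from 148960239 to 148961751 passed for day 1 in non-vaccinated mice (2.75, limma adjusted p = 0.0425; 0.0425 to 1 over its alternatives).

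The replicate numbers gave no sign of pairing: profiles with the same number had a mean correlation of -0.0158 over 45 pairs, and 1 of 18 arrays was most like its own number. Arrays were little alike in any case, with a median correlation of 0.0473 over all pairs, so pairing is not excluded. Not run were the filter on dim probes over all 18 arrays, which left 0 probes, and the alternatives on gene assignment, probe composition and gene lists. No probe had input well above background on more than 15 of the 18 arrays, and 7177 had it on at least 9.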

Other observations

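The tests in this part, splits included, were chosen after the results were seen. After realignment, profiles of arrays on the same slide were more alike than those on different slides, with a mean Pearson correlation across regions of 0.156 (9 pairs) against 0.0393 (two-sided permutation p = 0.00012 over 100000 resamples). Pairs on the same slide shared day and scan day and mostly the group, while the other pairs mixed these. The permutation did not keep days apart, so slide is not set apart from day, scan day and group. Arrays of the same group on different slides had a mean correlation of 0.103 (12 pairs), against 0.0335 for different groups on different slides (permutation p = 0.00028). Pairs of different groups mix arms, days and scan days, so this does not show that arrays of a vaccination arm are alike. All pairs lay between -0.16 and 0.409, and regions are not independent replicates.

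On the 10 arrays in place, 301 of 14216 regions were above the array median on at most 1 array, where shuffling regions within arrays gave 207 on average and 239 at most over 100 shuffles. At the other end, 83 regions were above it on at least 9 arrays, where shuffling gave 77.6 on average and 102 at most. A shared low methylation of some islands is a candidate explanation for the 301, as none of the 100 shuffles reached that count, but a likeness of arrays on the same slide, not set apart here, would raise it too.

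Splits of the same arrays gave these counts. For vaccinated against non-vaccinated mice, the real count was 2 at day 0, 0 at day 1 and 0 at day 8, and the highest of the other splits 0, 0 and 212, with as many as the real split in 1, 10 and 10 of 10 splits. For non-vaccinated mice at days 1 and 8 the real count was 0 and the highest other 1 and 0 (10 of 10 splits as many in both), and for vaccinated mice at day 1 it was 9 against 0 (1 of 10). With 10 splits, a share under 0.05 cannot be reached. The split with 212 exchanged non-vaccinated day 8 replicate 3 for vaccinated day 8 replicate 2, which put the 3 displaced day 8 arrays against the 3 in place, so it follows the grid.

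Averaged over the arms, day 8 against day 0 called 110 regions and the highest other of 100 splits 65, 1 of the 100 with as many. These splits break up slides, which each held 1 day only. Exchanging whole slides with the same arms between the days gave 33 as the highest of the others in 4 splits, too few for a share under 0.05. For vaccinated against non-vaccinated mice averaged over days and for the day 8 interaction, the real count was 0, which any split reaches (100 of 100), so these splits test nothing, with 7 and 88 the highest of the others. The split with 88 made the same exchange of 2 day 8 arrays as that with 212, so it follows the grid too.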
